A study of Mus musculus with 5 samples.

How the data were processed

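Organoids were grown from intestinal crypts of C57BL/6 mice in Matrigel, with EGF, Noggin, R-spondin, CHIR-99021, Y-27632, N-acetylcysteine, B27 and N2 in the medium, and treated for 3 days with vehicle, 25 µM AA or 50 nM PGE2 per the labels. The series design names the prostaglandin as a dimethyl analogue, and it is called dimethyl PGE2 throughout. Cells were released with TrypLE, sorted as DAPI-negative and made into 10x 3′ libraries. Per the submitters' processing notes Cell Ranger 4.0.0 and the mouse genome mm10 were used, and the deposited values are raw UMI counts per gene and cell barcode. The deposited barcode and feature lists hold names and no measurement (other). Counts were checked to be whole numbers of 1 or more, and each matrix had 28692 features. Whether the replicates came from different mice, cultures or days is not stated, so p-values measure only the spread between these samples, which may be technical.

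The 5 libraries were grouped by their titles: vehicle 1 and 2, AA 1 and 2, and dimethyl PGE2. The deposited names carry a prefix shared by vehicle 1 and AA 1 and another shared by the other 3 libraries, which is called the batch. The labels do not say what it marks. Between the batches 2018 genes were higher and 2361 lower in the second, and the difference between batches in vehicle and that in AA correlated across 14814 genes with r = 0.706, so the batch was taken as a pairing of the AA and vehicle libraries. Dimethyl PGE2 had 1 library, which gives no spread of its own and was assumed to vary like the others.

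Barcodes with at least 500 genes and at most 20% of UMIs from mitochondrial genes were kept. Doublets were removed by rank of the Scrublet score, at 0.8% per 1000 barcodes, because its automatic threshold found almost none. Of 4161, 8880, 4147, 8600 and 8954 barcodes in vehicle 1, vehicle 2, AA 1, AA 2 and dimethyl PGE2, 47.5%, 80.6%, 70.2%, 79.8% and 71.7% were kept. In vehicle 1, 45.3% of barcodes held more than 50% mitochondrial UMIs, against 6.91% in vehicle 2 and 21.3% in AA 1. Median genes per kept cell were 5788, 2891, 5669, 3083 and 3514. Clustering in scanpy 1.11.5 with leidenalg 0.10.2 used cells scaled to 10000 counts, 2000 variable genes centred within each library, 30 principal components, 15 neighbours, Leiden resolution 0.8 and seed 0. A cluster took the name of a class when 3 of that class's markers were detected as raised by 0.5 or more (log2, with 10 CPM added) and at least 2 of them were among its 10 leading genes. Class names are likenesses to marker lists and not sorted cell types. Stem-like cells were 1 cluster. Classes were tested where every library had at least 50 cells. Proliferating cells could not be tested in this clustering, because AA 1 held 8 of them, but were tested at resolution 0.4 and after thinning.

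UMIs were summed over the kept cells of each library, or over its cells of 1 class, and tested in edgeR 4.0.16 by quasi-likelihood with TMM scaling and filterByExpr, in 1 model of all 5 libraries. Adjusted p-values are Benjamini-Hochberg values, called under 0.05. The planned model held groups alone and left 2 residual degrees of freedom. Adding the batch, listed beforehand as an alternative and called the replicate block, left 1 and lowered the common dispersion from 0.123 to 0.0248. In 1 simulation per compound with 100 genes changed by 1 and 100 others by 2 on the log2 scale, the model without the batch found 0 of both, and the model with it found 72% and 100% for AA with 5 unchanged genes among its calls (2.82%). For dimethyl PGE2 it found 56% and 98%, with 21 unchanged genes (12%), above the rate aimed at. The simulated counts were drawn from the fit with the batch, with its batch differences and dispersions and the same compound effect in both batches. The simulations thus favour that model and cannot support choosing it, and their error rates hold only if its dispersions are right. SE is the fold change divided by the square root of its quasi-likelihood F, and 95% intervals use the matching t distribution. CPM use the TMM-scaled library size, and fold changes within a batch add a prior count of 2.

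Gene lists were tested with limma 3.58.1: camera with a preset correlation of 0.01, camera with the correlation estimated from these libraries, and fry, adjusted over the lists of 1 comparison. Lists with fewer than 4 tested members were only described. They covered stem, proliferating, enterocyte, goblet, Paneth, enteroendocrine, tuft, M cell, fetal and regenerative, immune, stromal and endothelial markers, signalling and stress targets, lipid and sterol metabolism, fat absorption, cell cycle, interferon, mitochondrial, p53 and chromatin genes. Some genes are in several lists.

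Genes were named by a rule: among those with an adjusted p under 0.05, a mean of at least 10 CPM and 1 direction in both batches, the 10 highest and 10 lowest fold changes of each comparison with vehicle (5 for AA against dimethyl PGE2 and within classes). Up to 4 members of each list described, and Lgr5, Ascl2, Olfm4, Clu, Ly6a, Ptgs2 and Ptger4, were also named. No gene passed without the batch, so the rule was applied to the model with it, a choice made after the values were seen. List members beyond 4 are named because they were called and were chosen after their values were seen, as were Reg4 and Ramp1 shares of cells. A few genes that the rule names are not reported here. The comparisons, tests, lists, rule and first set of alternatives were chosen before the data were examined.

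Shares of cells in a class were compared by an exact two-sided permutation test over 6 splits, with exact 95% binomial intervals per library. They came from a clustering that left out the 136 variable genes called in either comparison with vehicle. The test on doublets, and the starting values for the alternatives of shares, used the clustering on all variable genes. The likeness of the AA and dimethyl PGE2 effects was set against simulated unchanged groups, because both share the vehicle libraries. An interaction test with the library as a block compared the AA effect between stem-like and enterocyte-like cells. Free RNA of Fabp1 and the oxidation genes was judged against enteroendocrine-like cells, and that of the fetal and regenerative list against the whole library, because enteroendocrine-like cells held Ly6a with vehicle already. A count of 0 was bounded at 3 UMIs per library. Gene coordinates are those of GENCODE M21 on mm10 (GRCm38), where 257 of 258 named genes were found.

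Alternatives were DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, a mitochondrial limit of 10%, at least 1000 genes per cell, doublets kept, libraries thinned to the smallest, class mix equalised, resolution 0.4, no centring, clustering without called genes and leaving out each vehicle and AA library. Further ones chosen after seeing the data were cells with at least 5000 UMIs, cells thinned to 5000 UMIs before clustering, other classes, leaving out the dimethyl PGE2 library, and each alternative together with the replicate block. Splits of the samples and outlier tests do not apply to groups of 1 and 2 libraries. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3.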

Results

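Organoids grown from intestinal crypts of C57BL/6 mice are self-organising epithelial cultures that hold stem, proliferating and differentiated cells. They were kept for 3 days with vehicle, with 25 µM arachidonic acid (AA, an omega-6 polyunsaturated fatty acid), or with 50 nM dimethyl PGE2, a stable analogue of prostaglandin E2, which cells make from AA. Viable cells were sorted and their messenger RNA was counted by droplet sequencing with molecular identifiers (UMIs). The 5 libraries were 2 of vehicle, 2 of AA and 1 of dimethyl PGE2. The number of cells kept was 1975 and 7153 for vehicle 1 and 2, 2911 and 6862 for AA 1 and 2, and 6419 for dimethyl PGE2, and the kept cells held between 82831228 and 111350891 UMIs per library. Vehicle 1 and AA 1 formed a first batch with fewer and deeper cells (median 41047 and 35965 UMIs per cell), and the other 3 libraries formed a second batch (medians between 11929.5 and 15305). The series title concerns dietary AA and the stem cell state of the intestine, so the comparisons ask what AA changed, whether dimethyl PGE2 changed the same genes, and in which cells.

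A gene is said below to have risen or fallen where its adjusted p was under 0.05 in the edgeR model of whole-library counts that held the batch as a term. Fold changes are from that model unless stated otherwise, with their standard error (SE), and the level of a gene is in CPM, its counts scaled to the size of the library. The model without that term, planned as the first, called 0 genes in each of the 3 comparisons, and its values are given beside the results.

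With AA, the gene of stearoyl-CoA desaturase, Scd1, which puts a double bond into saturated fatty acids (ENSMUSG00000037071, chromosome 19, 44394455 to 44407879, minus strand), fell in both batches, from 168 to 45.1 CPM in the first and from 91.8 to 18.4 CPM in the second. It fell by 2.11 ± 0.21 SE on the log2 scale (adjusted p = 0.0076, n = 2 against 2 libraries). Ly6a, which encodes the surface protein Sca-1 and marks fetal and regenerating epithelium (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031, minus strand), rose by 1.25 ± 0.17 (adjusted p = 0.022). The stem cell genes Lgr5, Ascl2 and Olfm4 did not pass the test, with changes of -0.04 ± 0.26, 0.21 ± 0.19 and -0.07 ± 0.21 and 95% intervals of -0.65 to 0.57, -0.22 to 0.64 and -0.56 to 0.41. Lgr5 stood at 0.45 in the first batch and -0.52 in the second.

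In all, 107 of 14814 genes rose and 66 fell with AA. Among genes at a mean of 10 CPM or more, the highest changes included Capg, an actin-capping protein (2.98 ± 0.18) and Reg1, a secreted C-type lectin (2.97 ± 0.15). They also included Wfdc2, a secreted protease inhibitor (2.23 ± 0.17), the phospholipid-binding annexins Anxa1 (1.86 ± 0.23) and Anxa3 (1.63 ± 0.17), and Alpi, the alkaline phosphatase of the brush border (1.75 ± 0.14). The unnamed genes 4930461G14Rik (2.06) and CAAA01147332.1 (1.63) belonged to the same 10. Zg16, a lectin of goblet cell mucus, had the highest value (5.46 ± 0.31), but 1 cell held 84.8%, 54.5%, 25.7% and 50.9% of its UMIs in vehicle 1, vehicle 2, AA 1 and AA 2, so its size rests on a few cells. Besides Scd1, the lowest 10 held Sycn, a zymogen granule protein (-2.43), Gng11, a G protein subunit (-2.31), Nrn1 (-2.29), Clca4b (-1.48), G0s2, an inhibitor of triglyceride breakdown (-1.32), the histone gene Hist1h2bc (-1.26) and the transport protein Ttr (-1.24). Gm15284 (-1.73) and Cyp2c29 (-1.51) also fell. Gm15284, named Defa30 in the annotation, is a defensin with near-identical copies. Cyp2c29 stood at 40.1 and 15.3 CPM in the first batch against 1.16 and 0.329 in the second. Without vehicle 1 and the batch term Cyp2c29 was higher with AA (2.76, adjusted p = 0.0025). Without the batch term edgeR called 0 genes (322 at an unadjusted p under 0.05), and DESeq2 called 20, of which 19 were also called with the batch term. Cells were also drawn so that each library had the same mix of the classes with at least 50 cells in every library. Proliferating and Paneth-like cells were pooled with the unnamed cells there and so were not equalised, and AA 1 gave 424 cells. With this mix and the batch term 62 genes rose and 102 fell. The share of rises thus went from 61.8% to 37.8%. Without the batch term and with this mix, Ly6a stood at 0.41 and Anxa1 at 0.89.

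**Figure D1:**
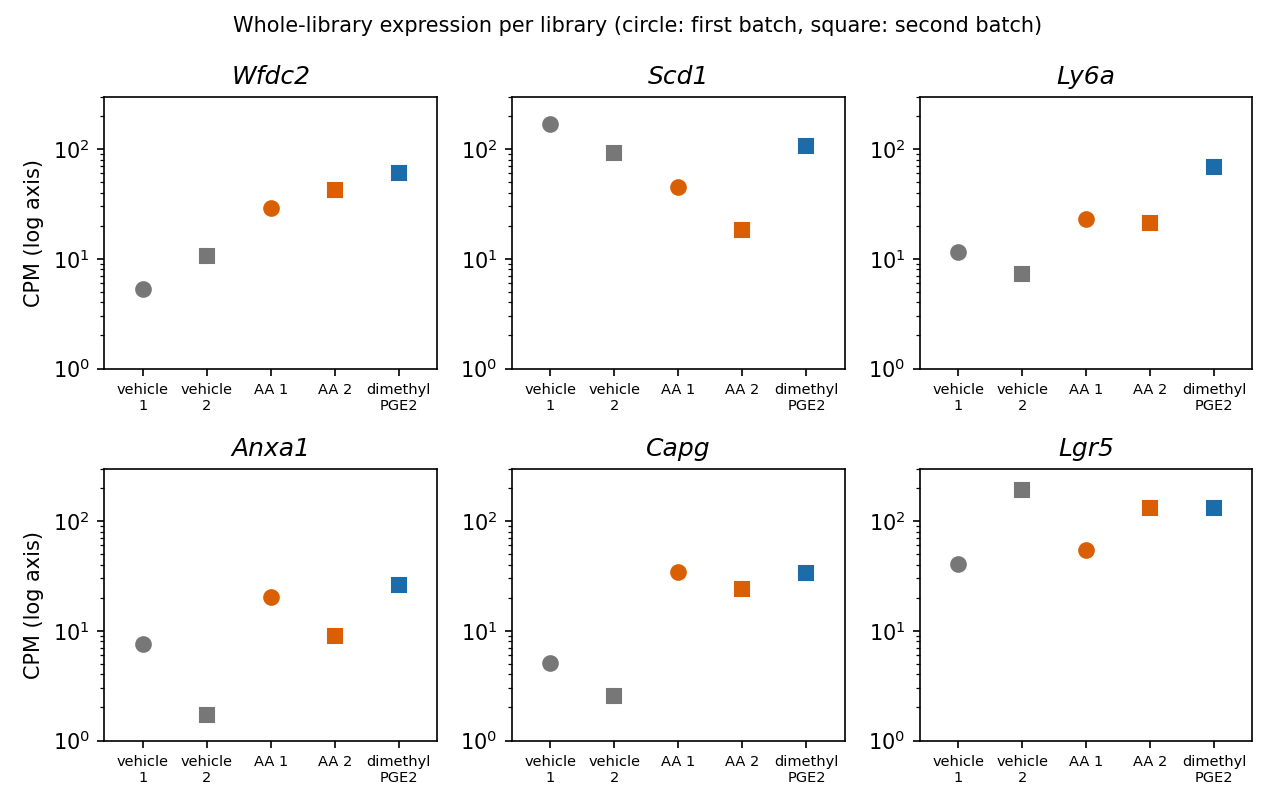
CPM (log axis) of Wfdc2, Scd1, Ly6a, Anxa1, Capg and Lgr5 in each of the 5 libraries, with circles for the first batch and squares for the second. Scd1 stands at 45.1 and 18.4 CPM in the AA libraries against 168 and 91.8 CPM with vehicle, while Ly6a is highest with dimethyl PGE2 (67.9 CPM).

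The list of fetal and regenerative epithelial genes rose with AA. Of its 16 tested members, 7 rose and none fell over all genes tested, and 13 rose when adjusted over the list alone. Besides Ly6a, Anxa1 and Anxa3, the 7 included the annexin Anxa10 (2.74 ± 0.17), the interleukin-1 receptor antagonist Il1rn (2.22 ± 0.34) and Emp1 (0.89 ± 0.15). The secreted chaperone Clu of the same list stood at 0.52 ± 0.19 (adjusted p = 0.281). The list's median was 1.40, with 1.24 in the first batch and 1.51 in the second. In limma's camera, which sets a list against all other genes with a preset correlation of 0.01, its adjusted p was 1.4e-31, and adjusted p = 0.636 with an estimated correlation.

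Genes of fatty acid oxidation and PPAR targets rose as a list with AA (25 tested, median 0.45, with 0.23 and 0.55 in the batches; camera adjusted p = 1.2e-11, and adjusted p = 0.636 with an estimated correlation). Over all genes 5 members rose and none fell, and 10 rose when adjusted over the list alone. Among them were Angptl4, a secreted inhibitor of lipoprotein lipase (1.32 ± 0.17), Cpt1a, which admits fatty acids to mitochondria (0.93 ± 0.14), the pyruvate dehydrogenase kinase Pdk4 (3.45 ± 0.52, under 1 CPM in every library) and the transcription factor Creb3l3 (1.56 ± 0.27). Fatty acid synthesis genes fell as a list of 14 (median -0.23, camera adjusted p = 0.0093, and adjusted p = 0.647 with an estimated correlation), but their members went both ways: adjusted over the list alone 5 fell and 2 rose, and over all genes Scd1 was the 1 member called. The fat absorption list of 17 shares Apoa1, Apoa4, Fabp1 and Fabp2 with the enterocyte markers. It rose (median 0.34, with 0.32 and 0.08 in the batches, camera adjusted p = 0.00043, and adjusted p = 0.636 with an estimated correlation). Over the list alone 3 members were up, and Mogat2, of triglyceride resynthesis, was up over all genes (0.99 ± 0.15). The sterol synthesis list of 22 did not pass (median -0.04, camera adjusted p = 0.844).

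Markers of differentiated cells moved in different directions with AA. Of 9 enteroendocrine markers, 8 fell when adjusted over the list alone and 3 over all genes: the tachykinin gene Tac1 (-1.15 ± 0.15), Chga of secretory granules (-1.22 ± 0.20) and the transcription factor Neurod1 (-0.98 ± 0.16). The list's median was -1.15, with -1.18 and -0.80 in the batches. Goblet markers rose (8 tested, median 0.78, with 0.67 and 0.28 in the batches). Of them 4 were up over the list alone and 2 over all genes, among them Muc2, the main gel-forming mucin (1.49 ± 0.16). Enterocyte markers rose (12 tested, median 0.52; 7 up and 1 down over the list alone), with Alpi past the test over all genes, and Paneth markers fell (7 tested, median -0.62; 4 down over the list alone), with the defensin Defa17 at -0.79. M cell markers rose (5 tested, median 0.93; 3 up over the list alone). Camera's adjusted p was 1.2e-11 for enteroendocrine, 2.2e-11 for goblet, 0.00016 for enterocyte, 0.0011 for Paneth and 0.0038 for M cell markers, and for each list adjusted p = 0.636 with an estimated correlation. The enterocyte and Paneth lists did not pass without the batch term (camera adjusted p = 0.100 and 0.0823). The Paneth list as tested lacks its member Defa30, because the counts hold it as Gm15284, which fell with AA. The stem, proliferating and tuft lists did not pass in either model, with medians of -0.09, -0.07 and -0.17 and camera adjusted p of 0.327, 0.991 and 0.78. Of the immune, stromal and endothelial lists only 3, 2 and 2 members were detected well enough to be tested, with medians of 0.63, -0.55 and -0.65.

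Of the interferon response list (16 tested, median -0.22), Isg15 (-3.39 ± 0.25) and Ifit1 (-3.37 ± 0.35) fell in both batches, at 3.34 CPM or less in every library, and 4 members fell and 1 rose over the list alone. The list fell (camera adjusted p = 0.00017, and adjusted p = 0.636 with an estimated correlation). NRF2 target genes (17 tested, median 0.29) and p53 target genes (15, median 0.31) each had 3 members up over the list alone and none over all genes, and glycolysis and hypoxia genes (22, median 0.28) had 1. Camera's adjusted p was 0.00036, 0.0038 and 0.024 for these lists, and adjusted p = 0.647, 0.636 and 0.636 with an estimated correlation. Nuclear genes of oxidative phosphorylation (26 tested) had a median of -0.50, but -0.07 in the first batch against -0.73 in the second, and the 13 genes of the mitochondrial genome a median of -0.52; none was called singly. Camera's adjusted p was 0.0030 and 0.00071 for these 2 lists, and adjusted p = 0.647 and 0.636 with an estimated correlation. The lists of Wnt targets (19 tested, adjusted p = 0.659), YAP targets (16, 0.38), Notch (8, 0.585), BMP targets (7, 0.772), cAMP and CREB targets (13, 0.0808) and eicosanoid genes (22, 0.62) did not pass in camera. Nor did those of S phase (22, 0.0833), G2M phase (23, 0.984), class II MHC (5, 0.731), unfolded protein and integrated stress (18, 0.703), dissociation stress (14, 0.991) and chromatin modifiers (32, 0.659). Ereg, an epidermal growth factor family ligand of the YAP list, rose singly (1.34 ± 0.23, adjusted p = 0.046). The prostaglandin receptor Ptger4 stood at 0.11 ± 0.15, and the cyclooxygenase gene Ptgs2 had 12 UMIs in all 5 libraries, too few to test.

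With dimethyl PGE2, genes of fetal and regenerative epithelium rose most. Ly6a went from 7.30 CPM in vehicle 2 to 67.9 CPM (log2 fold change 3.07 ± 0.23, adjusted p = 0.0023, n = 1 library against 2 of vehicle). Anxa1 (ENSMUSG00000024659, chromosome 19, 20373428 to 20390944, minus strand) rose by 3.62 ± 0.30. Anxa10 and Anxa3 rose by 4.20 ± 0.22 and 2.72 ± 0.23. Of the 16 tested members of that list 10 rose, and 15 when adjusted over the list alone; the median was 2.78, with 1.60 against vehicle 1 and 3.03 against vehicle 2. The members called also included Il33, an alarmin (3.33), Il1rn (3.83), Msln, mesothelin (4.04), the calcium-binding protein gene S100a6 (2.56 ± 0.40) and Emp1 (2.02). Camera gave adjusted p = 3.6e-69, and adjusted p = 0.756 with an estimated correlation, while limma's fry, which asks whether the genes move one way, gave 0.0328. Clu stood at 1.23 (adjusted p = 0.085). Lgr5, Ascl2, Olfm4 and Ptger4 did not pass (-0.31, 0.31, -0.44 and 0.25).

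In all, 128 genes rose and 12 fell with dimethyl PGE2. Of the genes at a mean of 10 CPM or more, the highest 10 also held Zg16 (7.17 ± 0.37, with 54.5% of the UMIs of vehicle 2 and 23.0% of those of the treated library in 1 cell), Reg1 (3.99), Capg (3.58), Wfdc2 (2.63), Muc2 (2.62 ± 0.20) and Lgals3, a galectin (2.62). The falls among them were Nrn1 (-1.58) and Cttnbp2 (-1.26). Goblet markers rose as a list (8 tested, median 1.25; 4 up over the list alone), as did enterocyte markers (12, median 0.85; 6 up) and fat absorption genes (17, median 0.45; 6 up). BMP targets rose (7, median 0.45; 2 up), namely the transcriptional regulators Id1 (1.53 ± 0.25) and Id3 (1.51 ± 0.23). So did M cell markers (5, median 1.01; 3 up), Paneth markers (7, median 0.54; 2 up) and the unfolded protein and integrated stress list (18, median 0.29; 3 up). Camera's adjusted p was 1e-16, 2.2e-10, 2.3e-06, 0.00065, 0.0157, 0.0227 and 0.00062 in that order, and for each list adjusted p = 0.756 with an estimated correlation. Tuft markers fell (8, median -1.41; 1 down over the list alone, camera adjusted p = 0.00072), as did nuclear genes of oxidative phosphorylation (26, median -0.83, 0.00074), with adjusted p = 0.756 for both with an estimated correlation. The enterocyte genes Alpi (2.08 ± 0.18), Apoa1 (2.56 ± 0.35) and Sis (1.40 ± 0.22) rose, and so did Ereg (2.59 ± 0.30). The list of fatty acid oxidation and PPAR targets did not pass (median 0.06, adjusted p = 0.814), nor did enteroendocrine markers (median -0.45, adjusted p = 0.0653), and Scd1 stood at 0.32 ± 0.26.

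The dimethyl PGE2 library lay in the second batch, and the batch term decides some of these results. Without it edgeR called 0 genes (214 at an unadjusted p under 0.05) and DESeq2 14, of which 13 were shared with the batch model. The enterocyte, fat absorption and Paneth medians turned negative without it (-0.83, -0.66 and -0.69), since they were -1.46, -1.04 and -1.32 against vehicle 1 but 0.93, 0.41 and 0.69 against vehicle 2. Those 3 lists and the M cell list did not pass without it (camera adjusted p = 0.274, 0.165, 0.766 and 0.204). The lists of fatty acid oxidation and PPAR targets (median -0.32, 0.035) and of enteroendocrine markers (-0.82, 0.00015) were called lower in that model alone, with adjusted p = 0.942 and 0.834 with an estimated correlation. The fetal list had a median of 2.02 there. The other lists had camera adjusted p between 0.0556 and 0.985 with the batch term.

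Set against each other (n = 2 libraries of AA against 1 of dimethyl PGE2), the compounds differed in lists of fatty acid oxidation and of fetal and regenerative genes. The compounds differ in structure, AA being an open-chain fatty acid and the prostaglandin carrying a cyclopentanone ring, and were given at different doses, 25 µM and 50 nM, for the same time, so their effects are not set side by side at a matched dose. Of 2 genes called with the batch term, Sst, the hormone somatostatin, was higher with AA (5.65, adjusted p = 0.0128); it lay under 10 CPM and was named after its values were seen. As a list, fatty acid oxidation and PPAR targets were higher with AA (median 0.32, camera adjusted p = 4.9e-15) and fetal and regenerative genes higher with dimethyl PGE2 (median -1.11, 7.1e-36), and adjusted p = 0.604 for both with an estimated correlation. BMP targets (-0.53), the unfolded protein and integrated stress list (-0.33) and Paneth markers (-0.84) were also higher with dimethyl PGE2, and tuft markers (1.12) and NRF2 targets (0.36) with AA (camera adjusted p between 8.2e-15 and 9.6e-05, and adjusted p = 0.604 with an estimated correlation). Enterocyte (-0.35), goblet (-0.40), fat absorption (-0.30), enteroendocrine (-0.26), cAMP and CREB target (-0.31), fatty acid synthesis (-0.26), class II MHC (-0.47) and interferon response genes (-0.08) were also lower and S phase genes (0.17) higher with AA, with the same p with an estimated correlation. The enterocyte and fat absorption lists were higher with AA instead without the batch term (0.93 and 0.77), and goblet, enteroendocrine, cAMP and fatty acid synthesis genes did not pass. The fetal and regenerative list stood at only -0.32 without it, with 6 of 16 genes above 0, and Paneth markers at 0.07. Stem markers (-0.16), Wnt targets (-0.31) and the mitochondrial genome (-0.56) were called lower and p53 targets (0.36) higher in that model alone, with adjusted p = 0.614 with an estimated correlation. Singly, Ly6a differed by -1.82 (95% interval -2.32 to -1.31, adjusted p = 0.099), Anxa1 by -1.76 (-2.39 to -1.13, adjusted p = 0.137) and Scd1 by -2.43 (adjusted p = 0.073), which did not pass. Without the batch term edgeR called 0 genes (86 at an unadjusted p under 0.05) and DESeq2 2.

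**Figure D2:**
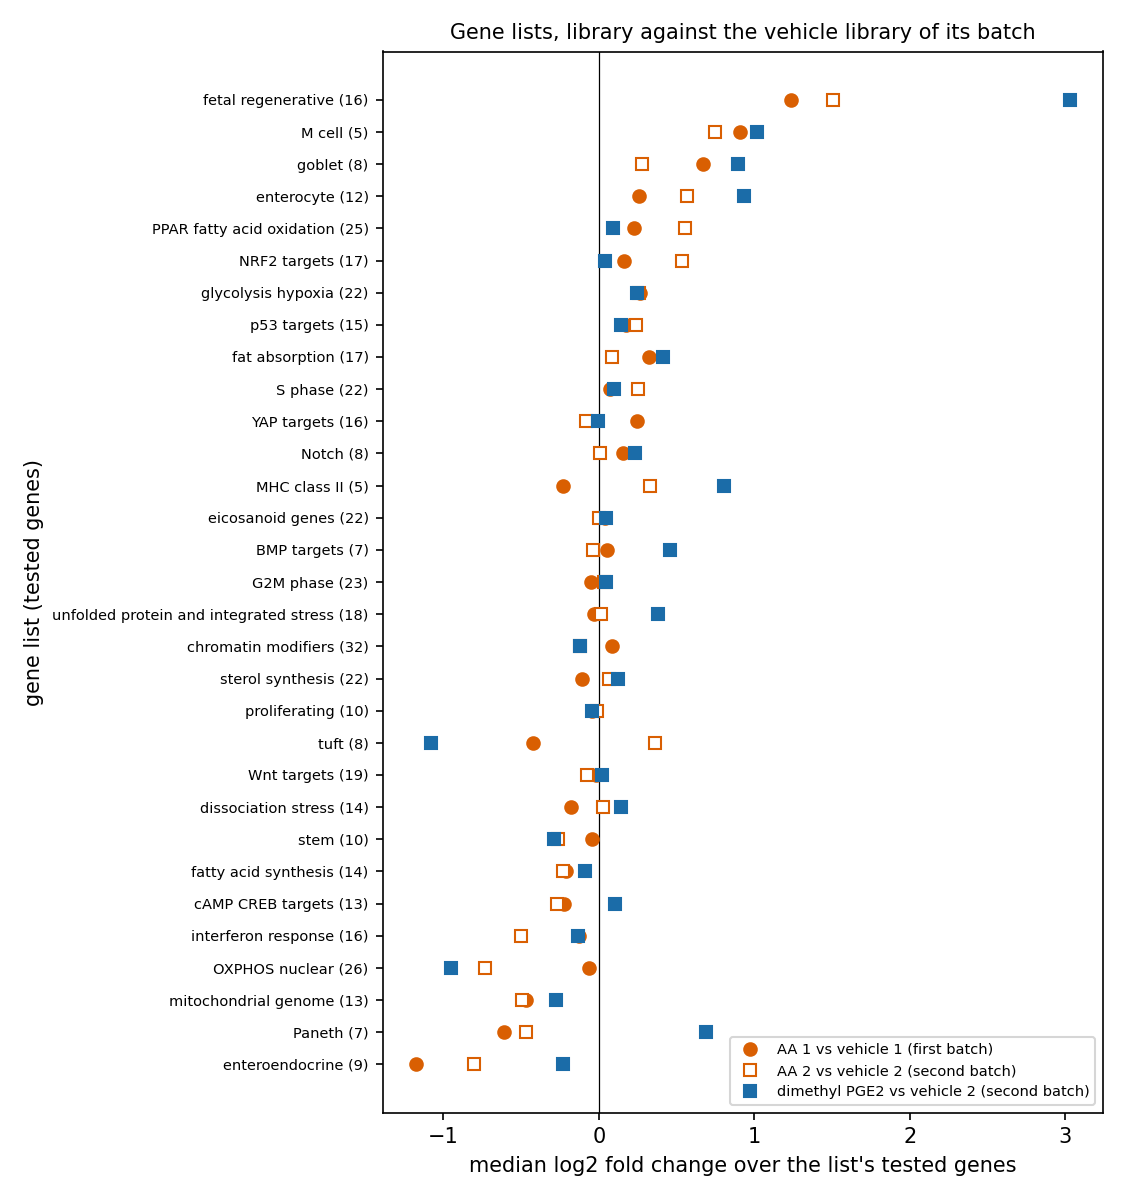
Median log2 fold change of the tested genes of each list, for AA 1 against vehicle 1, AA 2 against vehicle 2 and dimethyl PGE2 against vehicle 2. The fetal and regenerative list lies at 1.24, 1.51 and 3.03, and the list of fatty acid oxidation and PPAR targets at 0.23, 0.55 and 0.09.

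The genes that rose with AA and those that rose with dimethyl PGE2 overlapped in 68, out of 107 and 128, where independent lists of those sizes would share 0.925 and simulated unchanged groups set against the same vehicle libraries shared at most 2 in 20 simulations. Of the 66 and 12 genes that fell, 8 were shared (0.0535 for independent lists), and 1 gene was called in opposite directions. Neither figure shows what lists of these sizes would share through the shared vehicle libraries alone. Independent lists ignore that sharing, and unchanged groups give few calls to overlap. Across the 14814 genes, which are not independent replicates, the fold changes without the batch term correlated with r = 0.598. In 100 simulations of unchanged groups against the shared vehicles r was 0.287 on average and 0.307 at most. The covariance was 0.149 against a simulated 0.0421. With separate vehicle libraries for the 2 comparisons r was 0.341, with a simulated mean of 0.0008, and the covariance 0.109. With the batch term r was 0.703, where the simulations gave 0.382 on average and 0.411 at most. All these simulations draw genes independently from the fit with the batch term, which real libraries need not follow. Without vehicle 2, r was 0.787, below the simulated 0.834, so the excess is absent in that setting.

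Cells were clustered and named from markers fixed in advance. Within stem-like cells (between 64 cells in AA 1 and 1818 in vehicle 2), AA raised 64 and lowered 102 of 11992 genes with the batch term. Fabp1, the liver-type fatty acid binding protein, rose by 2.37 ± 0.27 (adjusted p = 4.5e-05), S100a6 by 2.32 ± 0.47 and Ly6a by 2.52 ± 0.47. Akr1b8, an aldo-keto reductase, and Wfdc2 rose by 2.27 and 2.20. Scd1 fell by 2.62 ± 0.29, and Sycn (-2.39), Nrn1 (-1.98), the metallothionein Mt2 (-1.95) and Gng11 (-1.83) fell too. Lgr5, Ascl2 and Olfm4 stood at -0.22 ± 0.27, -0.10 ± 0.24 and -0.09 ± 0.27 and did not pass. Within enterocyte-like cells 138 genes rose and 91 fell of 9353, led by Anxa10 (4.08 ± 0.35), S100a6 (3.32) and Capg (3.22), and by Gng11 (-3.79), Cyp2c29 (-2.26), the fatty acid desaturase Fads1 (-2.34 ± 0.26), Nrn1 (-1.94) and the immunoproteasome subunit Psmb8 (-1.89). Sprr2f led the rises by size, but 94.4% of its 36 UMIs in AA 1 and 80.5% of 77 in AA 2 lay in 1 cell each, with 0 UMIs in both vehicle libraries. Without the batch term edgeR called 0 genes in both classes (235 and 268 at an unadjusted p under 0.05), and DESeq2 called 7 in each.

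Dimethyl PGE2 raised 27 and lowered 32 genes within stem-like cells and raised 42 and lowered 24 within enterocyte-like cells. In stem-like cells Ly6a rose by 3.30 ± 0.50, Anxa3 by 2.55 ± 0.28, S100a6 by 2.43 and Wfdc2 by 2.09, along with 2210407C18Rik (1.88) and 4930461G14Rik (1.76), and the histone gene Hist1h2ap (-2.05), Smim4 (-1.71), Gm2000 (-1.63), Sp3os (-1.50) and Ttr (-1.43) fell. In enterocyte-like cells Anxa10 (4.69), Anxa3 (3.08), Capg (3.07), Reg1 (3.01, with 47.7% of its UMIs in 1 cell) and the mucin Muc3 (2.65) rose, and Cyp2c29 (-2.49), the calcium-binding protein S100g (-2.40), Gm933 (-2.33), Gm26917 (-2.10) and Rcor2 (-2.02) fell. Without the batch term edgeR called 0 genes (91 and 221 at an unadjusted p under 0.05), and DESeq2 called 1 and 4. Proliferating cells were too few to test in this clustering. At resolution 0.4 AA raised 174 and lowered 338 genes in them and dimethyl PGE2 raised 78 and lowered 221, and after thinning before clustering the counts were 128 and 147, and 44 and 29. In these settings edgeR called 0 without the batch term (219, 93, 264 and 128 at an unadjusted p under 0.05). The median of the fetal and regenerative list within stem-like cells was 2.03 with AA and 2.43 with dimethyl PGE2 (11 tested genes). Against the vehicle library of the batch it was 2.27 for AA 1, 0.83 for AA 2 and 1.24 for dimethyl PGE2. Within enterocyte-like cells the median was 2.24 with AA and 2.77 with dimethyl PGE2 (10 genes). That of fatty acid oxidation and PPAR targets within stem-like cells was 0.22 with AA, with 3 genes called of 22, and -0.05 with dimethyl PGE2.

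The share of cells in a cluster led by Ly6a, S100a6, Anxa1, Clu and Msln was higher in each treated library than in the vehicle library of its batch. Clustered without the genes called in either comparison, it held 1.01% of cells in vehicle 1 (exact 95% binomial interval 0.620% to 1.56%) and 0.657% in vehicle 2 (0.483% to 0.873%), 2.75% in AA 1 (2.19% to 3.41%) and 2.26% in AA 2 (1.92% to 2.64%), and 4.44% with dimethyl PGE2 (3.95% to 4.97%). The mean was 0.835% ± 0.251 (SD, n = 2) with vehicle and 2.50% ± 0.346 (SD, n = 2) with AA. At resolution 0.4 the Ly6a-led cluster was a broader one, with a mean of 12.6% of vehicle cells. It had 2 fetal and regenerative markers among its 10 leading genes, against 6 without the called genes. Its share was lower with AA instead (AA minus vehicle -1.33 percentage points). Stem-like cells were 8.35% and 28.1% of vehicle 1 and 2 and 2.16% and 24.3% of AA 1 and 2, with differences of -6.19 and -3.82 percentage points within the batches. Enterocyte-like cells were higher with AA by 3.99 and 1.17 points, and enteroendocrine-like cells differed by -1.49 and -0.117 points. Paneth-like cells were 4.10% and 0.461% of vehicle 1 and 2 and 4.19% and 1.17% of AA 1 and 2. Their share thus did not fall within either batch, unlike the Paneth markers. These shares differed more between batches than between groups, so leaving out 1 library changes the sign of the pooled difference. For stem-like cells it was -16.1 without AA 2, -14.9 without vehicle 1, 4.86 without vehicle 2 and 6.04 without AA 1, and for enterocyte-like cells 7.20, 5.79, -0.626 and -2.04. For enteroendocrine-like cells it ranged from -1.76 without vehicle 2 to 0.153 without vehicle 1, and for the Ly6a-led cluster from 1.42 to 1.91. The exact two-sided permutation test of 2 against 2 libraries cannot go below p = 0.333, so no share can pass it. Many cells stayed unnamed. An unnamed cluster held 17.0% and 38.1% of the cells of vehicle 1 and AA 1 but at most 0.117% of each second-batch library.

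**Figure D3:**
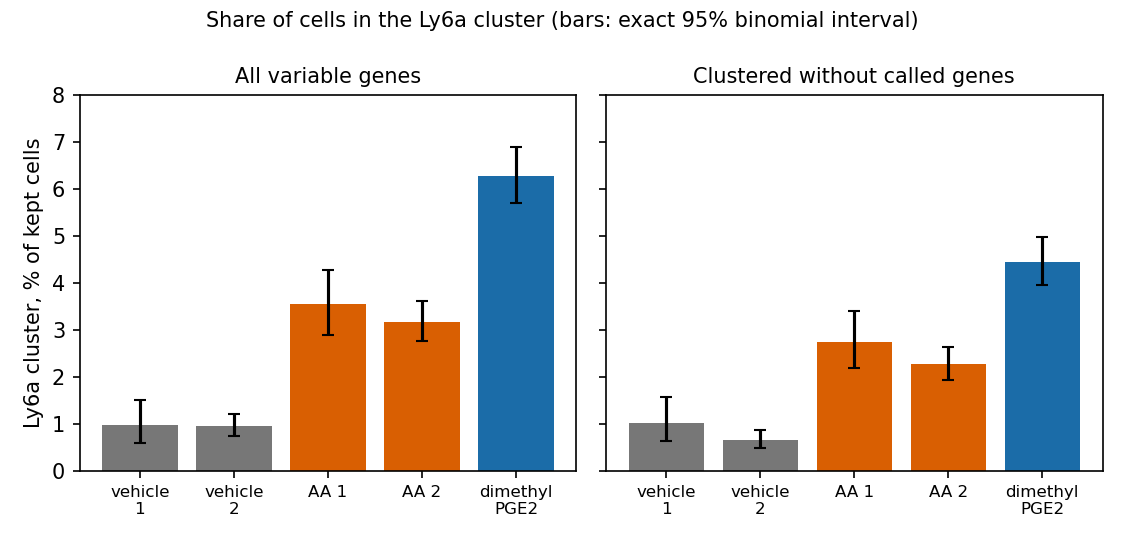
Percent of kept cells in the cluster led by Ly6a in each library, with exact 95% binomial intervals, when clustered on all variable genes and without the genes called. In the second setting it holds 1.01% and 0.657% of vehicle, 2.75% and 2.26% of AA and 4.44% of dimethyl PGE2 cells.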

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

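The test on free RNA from all cells that hold Fabp1 was chosen only after the result was seen, and the other test of this part before.

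The effect of AA on Fabp1, the liver-type fatty acid binding protein (ENSMUSG00000054422, chromosome 6, 71199827 to 71205023, plus strand), differed between enterocyte-like and stem-like cells in a test of the difference itself: -2.51 ± 0.27 on the log2 scale (adjusted p = 0.0083 in edgeR, 11099 genes tested, 422 at an unadjusted p under 0.05). In stem-like cells Fabp1 rose in both AA libraries (3.15 and 1.75 against the vehicle library of its batch), from 10.2 to 91.8 CPM and from 15.02 to 50.8 CPM, and stood at 11.7 CPM with dimethyl PGE2. In enterocyte-like cells it changed by 0.90 and -0.77, from 13575 to 25396 CPM and from 39210 to 22968 CPM. Across the whole library it did not pass the test.

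Free RNA of enterocyte-like cells entering stem-like droplets would raise the other enterocyte markers too. Fabp1 exceeded their median by 2.01 in the batch where it did so least. Markers with few counts in stem-like cells would show smaller fold changes in any case, because a prior count of 2 is added. The excess therefore cannot exclude such free RNA, which stays open. Free RNA from all cells that hold Fabp1 also stays open. Fabp1 had a UMI in 92.2% of stem-like, 72.9% of enteroendocrine-like and 85.2% of goblet-like cells of AA 1, and its rise in stem-like cells exceeded that in enteroendocrine-like cells by 0.69 in 1 batch and 2.56 in the other. Induction of Fabp1 by AA in cells of the crypt base may therefore be part of the pattern, or a rise of its RNA in many cell types or in the medium of the droplets may be, and these cannot be told apart.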

How the results depend on the processing

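The alternatives combined with the replicate block, cells with at least 5000 UMIs, cells thinned before clustering, the interaction with the block, leaving out the dimethyl PGE2 library, and the Ly6a cluster under other clusterings were chosen only after the result was seen; the others were planned. Where a result below changed, the cause was not tested.

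Without the batch, the whole-library count of 0 genes for AA went to 20 with the DESeq2 test, 9 with no filter on low counts and 173 with the replicate block, and without 1 library it ranged from 0 to 227 (227 without vehicle 1, 18 without vehicle 2, 1 without AA 1, 0 without AA 2, 0 without dimethyl PGE2). For dimethyl PGE2 the counts were 14, 10 and 140, and from 0 to 44 without 1 library (44 without vehicle 1, 18 without vehicle 2). For AA against dimethyl PGE2 they were 2, 2 and 2, and from 0 to 18. DESeq2 size factors, both other cell filters, doublets kept, thinning and the equalised class mix gave 0 again, but this model found 0 of the simulated changes, so those counts say nothing about stability. A vehicle or AA library left out together with the block leaves no residual degrees of freedom, so no such test exists. Without the dimethyl PGE2 library, AA against vehicle keeps 1, and with the block called 152 genes, all among the 173, with 180 in stem-like and 221 in enterocyte-like cells.

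With the replicate block as the starting point, the 173 genes of AA went to 307 with DESeq2 size factors, 823 with no filter, 427 with the mitochondrial limit of 10%, 442 with doublets kept and 372 in cells with at least 5000 UMIs. The 140 of dimethyl PGE2 went to 213, 603, 524, 335 and 268 in that order and to 71 with the class mix equalised. The 2 genes of AA against dimethyl PGE2 went to 7, 141, 323, 55 and 18, to 32 with the DESeq2 test, 4 with at least 1000 genes per cell and 13 with the class mix equalised. Of the counts with the block, 48 moved by more than 1.5 times and 32 did not. The balance of directions moved too. For dimethyl PGE2 the share of rises in the whole library, 91.4%, lay between 62.4% (no filter) and 91.5% (libraries thinned) under the alternatives. For AA against dimethyl PGE2 the share higher with AA, 100%, went as low as 5.56% in cells with at least 5000 UMIs.

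Within stem-like cells the 0 genes of AA went to 166 with the replicate block, 7 with the DESeq2 test and 42 with no filter, and without 1 library ranged from 0 to 57; with the block, 406 were called after thinning before clustering, 22 by DESeq2 and 336 with no filter. Within enterocyte-like cells they went to 229, 7 and 38, and from 0 to 27; with the block, 527 after thinning, 146 with DESeq2 size factors, 20 by DESeq2 and 572 at resolution 0.4. For dimethyl PGE2 the stem-like count went to 59, 1 and 8, and from 2 to 22; with the block, to 234, 4 and 209. The enterocyte-like count went to 66, 4 and 22, and from 0 to 29; with the block, to 392 after thinning, 38 with DESeq2 size factors, 9 by DESeq2 and 442 at resolution 0.4.

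Of the lists, camera called 13 for AA and 8 for dimethyl PGE2, and 15 and 10 with the replicate block. With an estimated correlation 0 were called for AA and 0 for dimethyl PGE2, with or without the block. Fry called 0 for both without the block, and with it 0 for AA and 2 for dimethyl PGE2. The other settings of both kept the number within 1.5 times. The genes whose AA effect differed between classes, 1 in the planned test, were 39 with no filter, 200 with the replicate block and 313 with the block after thinning.

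The correlation of the AA and dimethyl PGE2 effects ranged from 0.272 to 0.794 without 1 library. It was 0.787 without vehicle 2 and 0.695 without AA 1, where the simulated unchanged groups gave 0.834 and 0.694, so its excess over them was lost there. The covariance without AA 1, 0.201, and the share of genes with the same sign, 78.4%, stayed above the highest simulated values of 0.189 and 75.2%, while without vehicle 2 they were 0.309 and 80.6% against simulated means of 0.369 and 81.2%.

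Shares of cells depended on the clustering. AA minus vehicle was 16.1 percentage points for stem-like and 7.90 for proliferating cells with no centring. For the fetal and regenerative class it was 3.48, and 1.35 after thinning, 2.47 with doublets kept, 2.10 with no centring, 0.308 at resolution 0.4 and 4.44 without called genes. For the Ly6a cluster it was 2.39, and 2.85, 2.16, -1.33 and 1.67 after thinning, with no centring, at resolution 0.4 and without called genes. The cluster at resolution 0.4 was the broader one described above. Of the shares under alternatives, 11 differed from the starting value by more than the SD between libraries of a group and 68 by less. That SD spans both batches, so changes of sign count among the 68. Without 1 library, stem-like cells went from -6.05 to as much as 2.76 and enterocyte-like cells from 2.35 to as little as -2.08. The mean of the differences within batches, also among the 68, equals the starting value by arithmetic. The tally therefore does not measure stability.

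Of the named genes under alternatives, 532 values kept direction and stayed uncalled like the planned model, which could hardly call any, 85 passed it with the same direction, and 25 changed direction, among genes not called in the planned model. For AA, Olfm4 was -0.013 with the mitochondrial limit of 10% and -0.073 with the replicate block, Clu -0.063 with that limit and -0.48 with the class mix equalised, and Cyp2c29 0.98 with that limit. For dimethyl PGE2, Lgr5 was -0.37 with that limit and -0.31 with the block, Olfm4 -1.47 and -0.44, Clu -0.50 with the class mix equalised, and Ptger4 0.25 with the block. Without 1 library the AA values ranged from -1.06 to 1.23 for Lgr5, -0.56 to 1.10 for Ascl2, -1.16 to 0.88 for Olfm4, -0.10 to 1.25 for Clu, -0.61 to 0.80 for Ptger4, -4.06 to 0.50 for Gm15284 and -5.95 to 2.76 for Cyp2c29. Those of dimethyl PGE2 ranged from -0.53 to 1.71 for Lgr5, -0.28 to 1.00 for Olfm4 and -0.90 to 0.23 for Ptger4. Gm15284 and Cyp2c29 were highest without vehicle 1.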

Other observations

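The tests on free RNA of the Ly6a cluster, on free RNA from all cells for the oxidation genes, the ceiling from Fabp1, and all values in goblet-like and enteroendocrine-like cells were chosen only after the result was seen; the other tests were written before.

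In goblet-like cells (between 120 and 386 per library), 97 genes rose and 89 fell of 10802 with AA and the batch term, and with dimethyl PGE2 127 rose and 110 fell; without that term edgeR called 0 (220 and 208 at an unadjusted p under 0.05). DESeq2 called 6 and 6 without the batch term and 12 and 12 with it. Without 1 library and without the term edgeR called from 0 (without dimethyl PGE2) to 54 (without vehicle 1) for AA, and from 4 (without AA 1) to 26 (without vehicle 2) for dimethyl PGE2. Wfdc2 rose by 3.83 ± 0.37 with AA and 5.20 ± 0.40 with dimethyl PGE2, Ly6a by 2.77 ± 0.30 and 3.82 ± 0.34, and Reg4, a secreted C-type lectin of secretory cells, by 2.90 ± 0.37 and 3.67 ± 0.46. Reg4 had a UMI in 76.4% and 47.7% of goblet-like cells of AA 1 and AA 2 and in 57.7% with dimethyl PGE2, against 45.8% and 20.8% with vehicle. Ramp1, a coreceptor of the calcitonin family, had one in 55.7%, 17.6% and 36.9% against 33.3% and 6.05%, and rose by 3.34 ± 0.34 with dimethyl PGE2. Fabp1 rose by 3.33 and Scd1 fell by 2.34 ± 0.27 with AA in these cells. Zg16 rose by 5.38 and 6.998, but its UMIs lay in 5, 2, 52, 11 and 23 goblet-like cells of vehicle 1, vehicle 2, AA 1, AA 2 and dimethyl PGE2. Neurod1, a factor of enteroendocrine cells, fell by 2.52 ± 0.42 with dimethyl PGE2.

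In enteroendocrine-like cells (between 59 and 141 per library) AA lowered Scd1 by 3.68 ± 0.45, with a UMI in 6.78% and 1.65% of cells of AA 1 and AA 2 against 40.5% and 18.4% with vehicle, and raised Wfdc2 by 2.94 ± 0.33, found in 28.8% and 22.3% against 6.76% and 4.96%. With the batch term 26 of 9730 genes rose and 43 fell, and without it edgeR called 0 (169 at an unadjusted p under 0.05). DESeq2 called 5 without the term and 7 with it, and edgeR without the term 36 without vehicle 1, 28 without vehicle 2 and 0 without either AA library or dimethyl PGE2, where 17 were called with the term. Hormone genes had large fitted changes that rest on few cells. Neurotensin (Nts) had 86, 0, 1154 and 408 UMIs in 2, 0, 4 and 4 cells of vehicle 1, vehicle 2, AA 1 and AA 2, and 1 cell held 82.1% of those of AA 1. Somatostatin (Sst) had 388, 331, 1343 and 1595 UMIs in 3, 2, 3 and 5 cells, and 0 in 141 cells with dimethyl PGE2, where 3 UMIs would be 2.59 CPM of these cells. Peptide YY (Pyy) had 316, 1192, 5 and 89 UMIs in 6, 12, 3 and 3 cells. With so few cells these hormones show which cells were drawn as much as any effect of AA.

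The fetal and regenerative list was higher with AA and dimethyl PGE2. Doublets were tested on the share of the Ly6a cluster and not on the list itself. Among cells in the lower part of each library's doublet scores, that share was 3.38 or more times that of the batch's vehicle library. It was so in all 3 treated libraries, which argues against doublets for the share, though vehicle 1 had only 5 such cells. A larger Ly6a cluster with other cells as in vehicle predicted no change within stem-like cells, where the medians were 2.03 with AA and 2.43 with dimethyl PGE2. Against vehicle 2 alone they were 0.83 for AA 2 and 1.24 for dimethyl PGE2. The bound set for that test left out free RNA of the Ly6a cluster itself. Over the 11 genes tested in both, the medians within stem-like cells were set against those of the whole library. The smaller difference of the 2 comparisons was -0.13 and the larger 0.79. The larger lay outside the bound set for such free RNA, and both lay under the bound set against it. The medians therefore cannot tell whether such free RNA raised the list. In AA 1, Anxa1 (44 UMIs in 64 stem-like and 0 in 59 enteroendocrine-like cells), Ly6a (0.422 UMIs per stem-like and 0.0924 per enterocyte-like cell) and S100a6 (5.67 per stem-like and 1.03 per enteroendocrine-like cell) argue against it. In AA 2 Ly6a had 0.0277 and 0.0606, and Anxa1 42 UMIs in 1298 and 0 in 121 cells, too few to tell. S100a6 had 0.199 and 0.0909 per cell there (258 and 11 UMIs). With dimethyl PGE2, in the same order of classes, Anxa1 had 0.0741 and 0.0142 per cell and Ly6a 0.0756 and 0.05. S100a6 went the other way there, with 0.512 and 0.667. Ly6a stood at -0.21 in enteroendocrine-like cells with both compounds, but 20.3% and 7.80% of these cells held it with vehicle, which would hide a small rise, so more cells of this kind and a rise within stem-like cells may each be part of the pattern and cannot be told apart here.

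Of the oxidation genes called in the whole library, 4 were measured within stem-like cells, where 3 members of the list passed the test. The median change of the 4 there was at least 1.17 in each batch, which argues for these genes against more enterocyte-like cells as the whole cause. They had been selected by their rise in sums that include stem-like cells. All 22 members measured there had medians of 0.05 and 0.40 in the batches, so the list as a whole is not covered. The 4 exceeded the enterocyte markers within stem-like cells by 1.09 or more, but the 22 members did not in the first batch (0.05 against 0.08). A ceiling on free RNA of enterocyte-like cells took all Fabp1 of stem-like cells as such RNA. The set of called genes would then have 0.0489 and 0.00746 UMIs per stem-like cell in AA 1 and AA 2. There 2.36 and 1.24 were seen, which argues against such RNA as their source. Free RNA from all cells stays open. The set's UMIs per stem-like cell were 2.25 times those per enteroendocrine-like cell in AA 1 and 8.31 times in AA 2. With vehicle they were already higher, at 0.942 against 0.554 in vehicle 1 and 0.193 against 0.0284 in vehicle 2. The ratios thus hold a difference between the classes that is present without AA, and they cannot decide this. Activation of PPAR by AA or its products is a candidate explanation that no library here tests.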
